A study of Mus musculus with 6 samples.

How the data were processed

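Reduced representation bisulfite sequencing (RRBS) was done on DNA of GFP-positive cells sorted from mouse bone marrow, in 6 libraries that fall into 3 groups of 2. RRBS reads the methylation of cytosines in CpG-rich MspI fragments, so promoters and CpG islands are covered more densely than the rest of the genome. Per the labels' protocols, DNA was cut with MspI, size-selected, bisulfite converted and amplified, and each library was sequenced on a lane of its own on an Illumina HiScanSQ. Trim Galore, BSMAP, methylKit 0.9.1 and the mouse build mm9 are named in the submitters' processing notes. Their settings, the coverage filter and the statistical test are not given in the sources used here.

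The data used were the authors' tables of 3 comparisons, each a list of windows with a difference in methylation, and no value per library was analysed here. Per the file headers, each deposited row gives a window, a p-value, a q-value, a methylation difference, and the nearest transcription start site with its RefSeq transcript and gene symbol. The methylation difference is a signed score in percentage points that the authors computed between 2 groups, and no group mean stands beside it. In the deposited tables each window was 500 bp long and windows started 250 bp apart, so neighbouring windows share CpGs. The smallest absolute difference was 25.0 points and the largest q was 0.00995, so the tables hold windows past a threshold and not every window tested. The p-value was 0 as the authors deposited it for 70.9%, 68.7% and 81.9% of the windows of IDH1mut against IDH1wt, R-2HG against IDH1wt and R-2HG against IDH1mut. Windows that were repeated because 2 transcripts lay equally near were counted once, which took away 64, 4 and 1 rows. In the numbering of the windows 5, 2 and 1 numbers were absent, and those windows are not analysed here.

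The read depth per library and the coverage behind each window are unknown, and no interval that needs them is given. The labels do not say whether the 2 libraries of a group came from separate mice, so no p-value here covers more than these libraries, whose spread may be technical. Since the authors' test is not given, it is unknown whether their p-values and q-values include the spread between libraries or only the counting of reads. No own test between groups, no mean with an SD and no run without 1 library could be made from these tables.

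The sign of the difference is not stated in the deposited tables and was worked out as far as the values allow. For 3 groups the 3 differences must add up. Of the 4 possible sign orders, 1 gave a residual of 0 at the 3 windows listed in every table, and under it all 705 windows listed in exactly 2 tables had a remaining difference under 25 points. The other orders gave 248, 72 and 385 such windows. The table of IDH1wt with R-2HG therefore runs opposite to the other 2. Differences alone cannot fix which way round the whole set runs. Values were read as IDH1mut minus IDH1wt, R-2HG minus IDH1wt and R-2HG minus IDH1mut, since methylKit subtracts the control from the treated group, and with the group named second taken as treated, 2 of the 3 tables follow this order as they stand. Under the opposite reading every gain is a loss. Statements that IDH1mut and R-2HG moved the same way against IDH1wt hold under both readings.

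Windows within 1000 bp were joined into clusters, since neighbouring windows are not independent. The share of clusters with a gain was set against an even split with a two-sided exact binomial test and a Clopper-Pearson 95% interval, with Benjamini-Hochberg adjustment over the 3 comparisons. All clusters of a comparison rest on the same 2 libraries per group, so these tests treat clusters as independent and do not cover differences between libraries. Promoter windows lay from -2000 to 500 bp around the start site. Gains and losses in promoters, and the X chromosome against autosomes, were compared with two-sided Fisher's exact tests over clusters. For windows in 2 tables the remaining difference was obtained by subtraction. To see what shared controls give, 2000000 windows of 3 unchanged groups were simulated. The joining of windows and the sign order were tested on simulated data, where 4 of 4 sign orders and 300 of 300 clusters were recovered.

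The following choices were made before the data were examined: the tests, the alternatives to be tried, 15 gene lists with 318 genes, and the rule for named genes. For each comparison this rule takes up to 20 members of the lists in order of listed windows and then size, the 8 genes with most windows, the genes of the 5 largest gains and the 5 largest losses, and Idh1, Hoxa9, Tet2 and Dnmt3a. The plan was to assign windows to a gene or its promoter. No mm9 annotation was used here, so each window was given to the authors' nearest start site at any distance, and exon, intron and UTR are not given. Some listed genes are not reported here. A gene symbol therefore says which start site is nearest, not that the window regulates it. The authors' transcripts were matched to RefSeq symbols of GRCm38.p6 by name only, for 875 of 885, 450 of 454 and 363 of 370 transcripts. Without the list of all windows tested, no enrichment of a gene list and no overlap expected of independent lists could be computed. Alternatives were a larger difference, a smaller q, other cluster distances, other promoter limits, leaving out X and Y, other rules for a shared position, a distance limit of 50 kb, and some added later. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.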

Results

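DNA methylation was measured by RRBS in mouse bone marrow cells that had been immortalised with HoxA9, a homeobox transcription factor that drives self-renewal of myeloid progenitors. The cells were transduced with wild-type IDH1 (IDH1wt, 2 libraries) or with IDH1 carrying the R132C mutation (IDH1mut, 2 libraries). Others received an empty vector and were carried in mice given R-2HG at 1 mg per day for 4 weeks (R-2HG, 2 libraries). GFP marks the transduced cells, which were sorted 4 weeks after transplantation or treatment. Wild-type IDH1 turns isocitrate into 2-oxoglutarate, and the mutant enzyme makes R-2-hydroxyglutarate (R-2HG), which competes with 2-oxoglutarate at TET enzymes and other dioxygenases. The 3 comparisons ask which regions change methylation with the mutant enzyme, which change in cells exposed to its metabolite, and where the 2 differ. The R-2HG cells carry an empty vector and the IDH1wt cells a transgene, so their comparison does not isolate the metabolite. Read depth is unknown, and the values are the authors' differences between groups without replicate error. Gains and losses follow the sign reading in the methods, which the data fix only up to a reversal of all directions.

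Against IDH1wt, IDH1mut cells gained methylation near Mab21l2, Bmi1, Gata3, Hoxa5, Hoxb3 and Hic1 and lost it at Hoxc6, Cdkn1c and Igf2. In the authors' deposited table, differences were listed for 1493 windows near 881 genes, 1035 of them gains and 458 losses. The gains had a median of 30.6 percentage points (quartiles 27.1 and 36.5) in the authors' deposited table, and the losses a median of -28.9. Joined into 927 clusters, 622 were gains and 305 losses, a share of gains of 67.1% (95% interval 64.0 to 70.1, exact binomial p = 1.04e-25, adjusted p = 3.11e-25). Under the other sign reading these gains are losses.

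Of the 39 developmental homeobox and Polycomb target genes, 5 were listed for IDH1mut as the nearest gene. All 5 were gains: Gsc, Hoxb3, Hoxb4, Six2 and Irx3. Irx3 was in the preset list, but it fell outside the rule for named genes and was named after its values were seen. Counting promoter windows only, 1 of the 5 was left, Hoxb3. The windows of Gsc, Six2 and Irx3 lay far from the start site, at -81306, -112408 and -165699 bp in the authors' deposited table. Hoxb3 gained 31.5 to 36.5 points in 3 windows from -1333 to -2833 bp of its start site (chromosome 11, 96201751 to 96203750), and Hoxb4 gained 28.8 and 31.5 points in the authors' deposited table. Of the 19 stem and progenitor genes 4 were gains and 1 was a loss. Bmi1, a Polycomb protein needed for stem cell self-renewal, gained 41.8 to 53.7 points in 3 windows from 3608 bp downstream of its start site in the authors' deposited table (chromosome 2, 18602251 to 18603250). Etv6, a repressor required by blood stem cells, gained 44.7 points at 52778 bp, and Gata2, a stem cell transcription factor, gained 41.6 points at -46158 bp in the authors' deposited table. Prdm16, a list member named after its values were seen, also gained. Hlf lost methylation, with a difference of -28.9 points at 42482 bp in the authors' deposited table.

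In the HoxA9 and Meis1 programme 2 of 18 genes were listed for IDH1mut. Hoxa5, a neighbour of Hoxa9, gained 30.8 to 35.5 points in 4 windows over and downstream of its start site in the authors' deposited table (chromosome 6, 52153501 to 52154750). Meis1, the cofactor of HoxA9, had 3 gains of up to 44.6 points at 143223 bp downstream of its start site and 1 loss of -42.4 points at 10973 bp in the authors' deposited table. Hoxa9 itself was not listed in any comparison. Of the 25 Wnt and Notch genes, the Wnt receptor genes Fzd1 and Fzd2 gained 33.8 and up to 29.4 points, and Ctnnb1, which encodes beta-catenin, was a loss with -29.3 points at 142557 bp in the authors' deposited table. Notch3, a list member named after its values were seen, was the remaining one and a gain. Among 23 tumour suppressors often hypermethylated in cancer, the repressor gene Hic1 gained 29.7 to 35.5 points in 4 windows in the authors' deposited table. The cytokine signalling inhibitor Socs3 gained 31.9 points at 19181 bp in the authors' deposited table. Gata4 was a loss with -36.8 points at -27155 bp in the authors' deposited table. Esr1, a list member named after its values were seen, was also a loss.

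The cell cycle inhibitor Cdkn1c, the only one of 19 cell cycle genes listed for IDH1mut, was a loss with -36.5 and -37.0 points over its start site in the authors' deposited table (chromosome 7, 150646751 to 150647500). The imprinted growth factor gene Igf2 was a loss with -32.9 and -33.7 points at its start site in the authors' deposited table. Another of the 26 imprinted genes, Nnat, named after its values were seen, was a gain. Of 21 MAPK genes the ERK phosphatase gene Dusp6 was listed, with a gain of 36.7 points at -58615 bp in the authors' deposited table. Among the 15 genes of DNA methylation and TET machinery, the methyltransferase gene Dnmt3a gained 25.8 points over its start site in the authors' deposited table (chromosome 12, 3891501 to 3892000). Tet2 was not listed in any comparison, nor was Idh1 or another of the 13 genes of IDH and 2-hydroxyglutarate metabolism. No myeloid differentiation gene of 25 and none of the 26 other 2-oxoglutarate-dependent enzymes was listed for IDH1mut. Of the lists for other cell types, 1 of 21 lymphoid genes was listed, Gata3, with 33.3 to 48.8 points in 3 windows downstream of its start site in the authors' deposited table. The single listed members of the erythroid and stromal lists, Zfpm1 and Col1a1, were gains and were named after their values were seen.

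Outside the lists, the largest gain was at Mab21l2, a developmental gene, with 60.8 to 69.6 points in 4 windows just downstream of its start site in the authors' deposited table (chromosome 3, 86350751 to 86352000). The polyubiquitin gene Ubb gained 65.5 and 67.4 points and the pseudogene Hmga2-ps1 62.6 points in the authors' deposited table; reads of both may be shared with near-identical copies. Hoxc6, a homeobox gene outside the lists, had the most windows, 8 losses of -29.9 to -58.1 points around its start site in the authors' deposited table (chromosome 15, 102835751 to 102842250). Lrrc4 and the microRNA gene Mir671 had 7 gains each, of up to 58.4 and 52.9 points in the authors' deposited table. Mir684-1 had 5 gains, but on chromosomes 16, 2 and 5, so these are 3 loci under 1 symbol. Mis18a had 5 gains, Neurl1a 5 losses, and Dsel and Grik3 windows in both directions. The nearest windows of Mis18a, Neurl1a and Dsel lay at 27367, 31670 and 109996 bp in the authors' deposited table. Hccs and 4930401O10Rik were among the 5 largest losses, with -55.6 and -56.0 points in the authors' deposited table. The authors' q was 8.8e-05 at Hccs and 0 at 4930401O10Rik. Promoter windows made up 18.1% of the list. Of the gained clusters 18.5% lay in promoters and of the lost clusters 14.4%, a difference that did not pass Fisher's exact test (odds ratio 1.35, p = 0.138, adjusted p = 0.414).

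**Figure D1:**
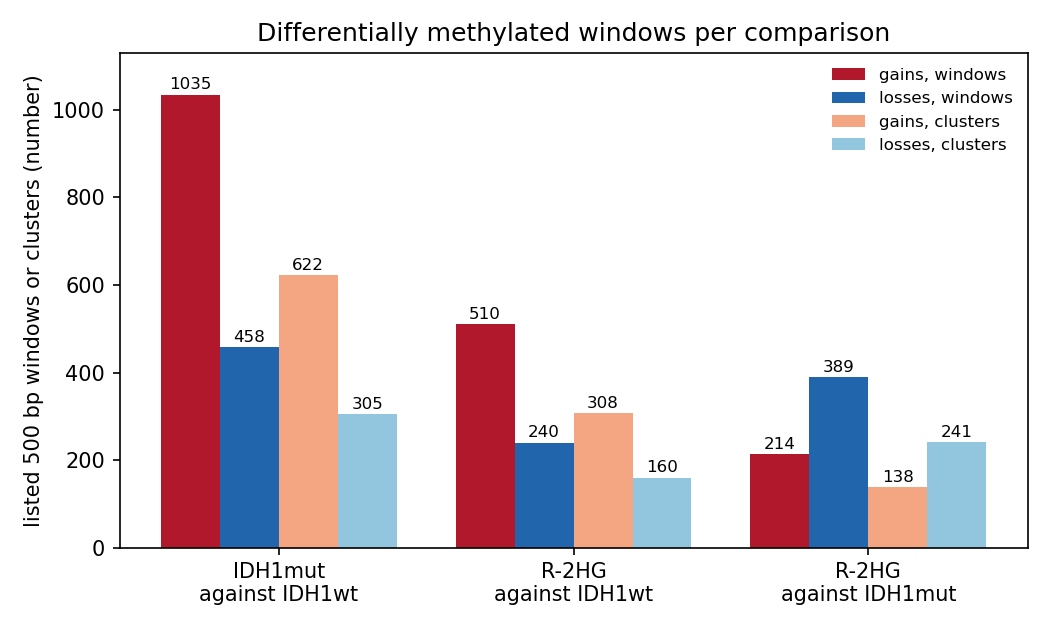
Number of listed 500 bp windows (dark bars) and of clusters of windows within 1000 bp (light bars), gains in red and losses in blue, for the 3 comparisons. Gains outnumber losses against IDH1wt (1035 to 458 and 510 to 240 windows) and losses outnumber gains in R-2HG against IDH1mut (389 to 214), under the sign reading given in the methods.

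Against IDH1wt, R-2HG-treated cells gained methylation near Hoxb3, Dll4, Hic1 and Zfp503 and lost it at Hoxc6 and Cdkn1c. In the authors' deposited table, differences were listed for 750 windows near 452 genes, 510 gains with a median of 29.4 points and 240 losses with a median of -28.6. Of 468 clusters 308 were gains, 65.8% (95% interval 61.3 to 70.1, exact binomial p = 7.29e-12, adjusted p = 1.09e-11). This comparison differs in the vector as well as in the treatment, and under the other sign reading its gains are losses.

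Of the developmental homeobox and Polycomb target genes, 4 were gains in R-2HG, Hoxb3, Evx1, Nkx6-1 and Six2, and Irx3 was a loss. Counting promoter windows only, 2 of them were left, Evx1 and Hoxb3, and the windows of Nkx6-1 and Six2 lay at 125231 and -112408 bp in the authors' deposited table. Hoxb3 gained 26.1 to 34.5 points in 5 windows, Evx1 32.5 points at -742 bp and Irx3 was a loss with -38.8 points at -165199 bp in the authors' deposited table. The stem and progenitor genes Etv6, Prdm16 and Hmga2 were gains, of 34.9 points at 52778 bp, up to 26.9 at -4520 bp and 26.9 at -75011 bp in the authors' deposited table. In the Wnt and Notch list, the Notch ligand gene Dll4 gained 28.8 to 36.0 points in 4 windows upstream of its start site in the authors' deposited table (chromosome 2, 119147501 to 119148750). Fzd1 gained 26.6 points, and Wnt5a was a loss with -26.4 points at -134659 bp in the authors' deposited table. Hic1 gained 25.6 to 28.4 points, Hoxa5 26.8 points and Dusp6 29.9 points in the authors' deposited table, each as the single member of its list. Cdkn1c was a loss with -33.8 and -36.7 points in the authors' deposited table. Of the 26 other 2-oxoglutarate-dependent enzymes the histone H3K27 demethylase gene Kdm6b was listed, with 25.3 points at -7825 bp in the authors' deposited table. Of the lymphoid genes the B cell factor gene Ebf1 gained 41.6 points at 2867 bp in the authors' deposited table. No member of the myeloid, erythroid, stromal, imprinted, DNA methylation or IDH metabolism lists was listed for R-2HG.

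Zfp503 had the most windows for R-2HG, 9 gains of 28.7 to 47.8 points downstream of its start site in the authors' deposited table (chromosome 14, 22801501 to 22805250). Hoxc6 had 6 losses of -35.5 to -45.3 points and Mir671 5 gains of up to 33.8 points in the authors' deposited table. The largest gains lay near Vmn1r52, Ubb and Lhcgr, the luteinising hormone receptor gene, with 62.0, 61.2 and 58.9 points in the authors' deposited table. Snx6, a sorting nexin gene, had the largest loss, -61.9 points at 12400 bp in the authors' deposited table, followed by A330009N23Rik and B020004J07Rik. The authors' q at these 3 was 1.3e-07, 1.6e-10 and 1.5e-06, while 68.7% of the windows had a p of 0. Dsel, Gm1821, Msl3l2 and Gm12718 were the other genes with the most windows. Promoter windows made up 13.3% of the list, with 13.6% of gained and 16.3% of lost clusters in promoters (Fisher's exact test, odds ratio 0.814, p = 0.490).

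The lists for IDH1mut and R-2HG shared 388 windows, 26.0% of the former and 51.7% of the latter, and all 388 moved the same way, 306 as gains and 82 as losses. Both use the same IDH1wt libraries. Simulated unchanged groups sharing their controls moved the same way in 99.1 to 100% of the windows past both thresholds, and 6.07 to 27.7% of one list was in the other, over thresholds of 1.5 to 3 SD of a difference. The simulated lists were of equal length, unlike the 1493 and 750 windows here, so these shares cannot be set side by side. The controls could not be split, so an unknown part of the overlap can come from them. Etv6, Hoxb3, Hoxa5, Hic1, Fzd1, Dusp6, Six2, Prdm16 and Cdkn1c were the preset genes with a shared window. At Cdkn1c the differences were -37.0 and -36.7 points, and at Hoxb3 36.5 and 34.5 points, in the authors' deposited table of each comparison.

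Set directly against IDH1mut, R-2HG cells had lower methylation in windows nearest to Bmi1, Gata3 and Fzd2 and in 1 window at a Dnmt3a start site. They had higher methylation in windows nearest to Mab21l1, Ltb4r1 and Col1a1. In the authors' deposited table, differences were listed for 603 windows near 369 genes, 214 gains with a median of 29.0 points and 389 losses with a median of -29.2. Of 379 clusters 138 were gains, 36.4% (95% interval 31.6 to 41.5, exact binomial p = 1.36e-07, adjusted p = 1.36e-07). The vector differs here too, and the other sign reading reverses these directions.

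Bmi1 and Gata2, the listed stem and progenitor genes, were lower in R-2HG, Bmi1 with -31.4 to -44.8 points in 3 windows and Gata2 with -27.2 points at -46158 bp in the authors' deposited table. Fzd2 was lower, with -25.1 to -33.8 points in 4 windows, and Notch3, a Notch receptor gene, had 1 window at -28.1 and 1 at 26.5 points in the authors' deposited table. Gata3 was lower, with -29.6 to -40.3 points in the same 3 windows that were gains in IDH1mut, in the authors' deposited table. Dnmt3a was lower in 1 window, with -35.8 points at the start site of the nearest transcript in the authors' deposited table (chromosome 12, 3891751 to 3892250). This window overlaps the Dnmt3a window that gained in IDH1mut, but was itself not listed against IDH1wt. Of the 39 developmental homeobox and Polycomb target genes, Irx3 and Hoxc10 were listed and both were lower. Their differences were -31.2 to -40.3 points from -165199 to -165699 bp and -26.2 points at 26 bp in the authors' deposited table. In the HoxA9 and Meis1 programme Hoxa10 was higher by 28.6 points and Meis1 lower, with -25.1 and -25.9 points in the authors' deposited table. Windows nearest to Gata4 and Esr1, at -27155 and 99996 bp, were higher by 33.4 and 39.3 points in the authors' deposited table. The stromal genes Col1a1 and Lepr were higher by up to 33.9 and 27.6 points in the authors' deposited table. No myeloid, erythroid, MAPK, cell cycle, imprinted, IDH metabolism or other 2-oxoglutarate-dependent gene of the lists was listed.

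Mab21l2 was lower in R-2HG, with -32.8 to -42.3 points in 4 windows, and its paralogue Mab21l1 higher by 28.1 to 42.7 points in 4 windows, in the authors' deposited table. Mmp23 and Fmn1 were lower in all their windows, reaching -37.6 and -48.1 points, and the leukotriene receptor gene Ltb4r1 was higher by 44.6 to 47.8 points in the authors' deposited table. The other genes with most windows were 1700030C10Rik, with 6 losses, and Skor2, with windows in both directions. The largest gains lay near Ppa1, 4930401O10Rik, Mir5103 and Ociad2, with 61.7, 51.9, 48.2 and 48.2 points in the authors' deposited table. The largest losses were in windows nearest to Bach1, Kcnj14, Zfp36l1 and Fam171a2, with -54.6, -54.0, -51.8 and -51.0 points in the authors' deposited table. Those of Bach1 and Zfp36l1 lay at 98304 and 89501 bp. The authors' q was 7.4e-05 at Ppa1, 4.4e-05 at Kcnj14 and 0.00185 at Zfp36l1, and 0 at the others of these largest differences. The differences between R-2HG and IDH1mut do not by themselves say which group moved. Against IDH1wt, IDH1mut was listed at 4930401O10Rik, Mir5103, Bach1 and Mab21l1, with -56.0, -37.9, 59.5 and -31.5 points. Subtraction gave R-2HG -4.15, 10.4, 4.91 and 11.2 points there. At Fam171a2, Kcnj14 and Ltb4r1 R-2HG was listed instead, with -52.8, -44.7 and 28.8 points. Subtraction gave IDH1mut -1.78, 9.26 and -19.0 points there. Of gained clusters 16.7% and of lost clusters 21.6% lay in promoters (Fisher's exact test, odds ratio 0.727, p = 0.285). The share of clusters on the X chromosome was 3.45%, 3.63% and 2.64% in the 3 comparisons, with no difference past Fisher's exact test (p = 0.878, 0.495 and 0.439). These tests set pairs of lists against each other as if independent, although the lists share windows and libraries, so they decide little.

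Of the 705 windows in exactly 2 tables, IDH1wt stood apart from both other groups in 385, IDH1mut in 248 and R-2HG in 72. Over 435 clusters the shares were 53.8% (95% interval 49.0 to 58.6), 35.6% (31.1 to 40.3) and 10.6% (7.85 to 13.9). Against an even share among the 3 groups, exact binomial tests gave p = 2.44e-18, 0.309 and 3.13e-28. The tests in this paragraph treat clusters as independent although all rest on the same 2 libraries per group. They do not cover differences between libraries, and the 3 shares are not independent of each other. IDH1wt was the lower group in 179 of its 234 clusters (76.5%, exact binomial p = 1.66e-16), and IDH1mut the higher group in 101 of its 155 (65.2%, exact binomial p = 0.000199). R-2HG was the higher group in 19 of its 46 clusters (41.3%, exact binomial p = 0.302). Where IDH1wt stood apart, the difference was larger for IDH1mut than for R-2HG in 181 of 234 clusters (77.4%, exact binomial p = 1.48e-17), with median absolute differences of 35.5 and 30.4 points. Bmi1, Fzd2, Gata2, Gata3, Gata4, Meis1 and Notch3 had windows in which IDH1mut stood apart, and at Irx3 1 window set IDH1mut apart and 1 set R-2HG apart. At Bmi1 the difference was 53.7 points for IDH1mut in the authors' deposited table, and subtraction gave 8.96 points for R-2HG. Standing apart means only that the third difference was not listed. At the window with the largest IDH1mut difference, subtraction gave R-2HG 14.4 points at Gata2, 14.8 at Gata3 and 19.5 at Meis1. There R-2HG lay between the other groups. It gave -4.38 at Fzd2, -3.40 at Gata4 and -0.905 at Notch3. Windows of 2 genes were in every table. At Mab21l2 the differences were 69.6 for IDH1mut and 36.7 points for R-2HG in the authors' deposited table, and at Aqp12, chosen after its values were seen, 57.1 and 28.5.

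**Figure D2:**
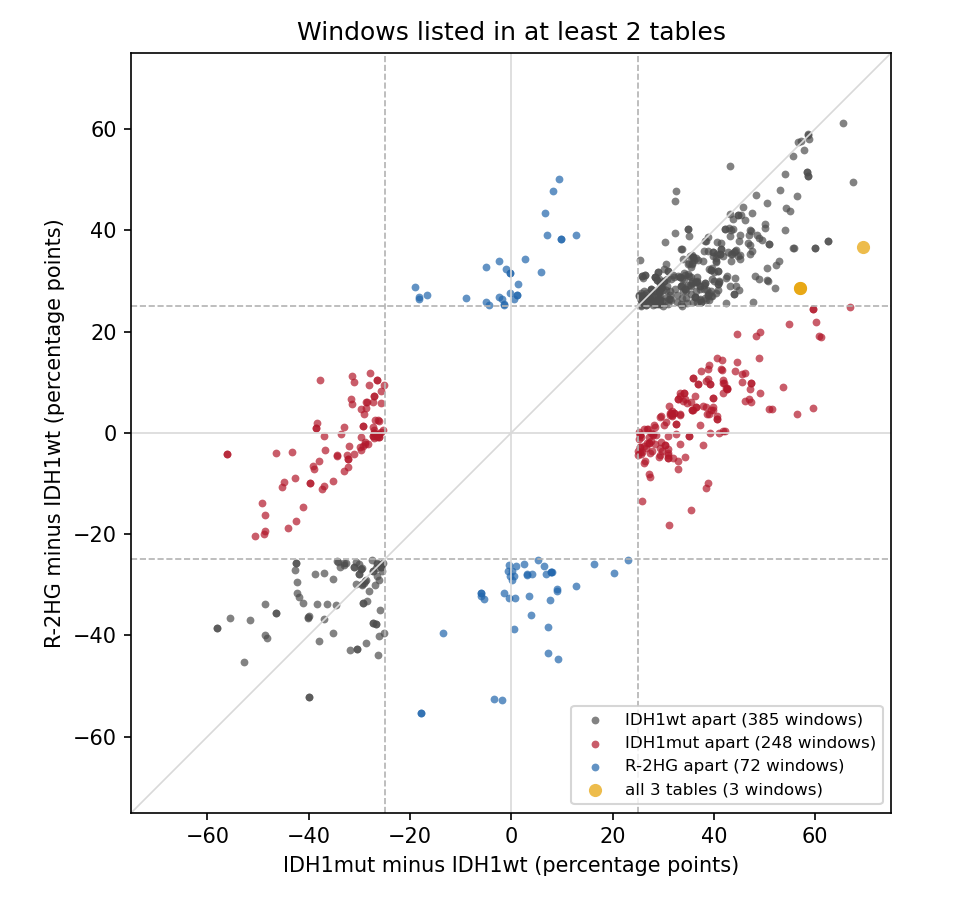
Difference against IDH1wt in IDH1mut (x axis, percentage points) and in R-2HG (y axis, percentage points) for the windows in at least 2 tables, coloured by the group that stands apart, with differences not listed obtained by subtraction and dashed lines at 25 points. The 385 windows in which IDH1wt stands apart lie in the upper right and lower left corners, which follows from their definition, and IDH1wt is the lower group in 303 of them under the sign reading given in the methods.

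**Figure D3:**
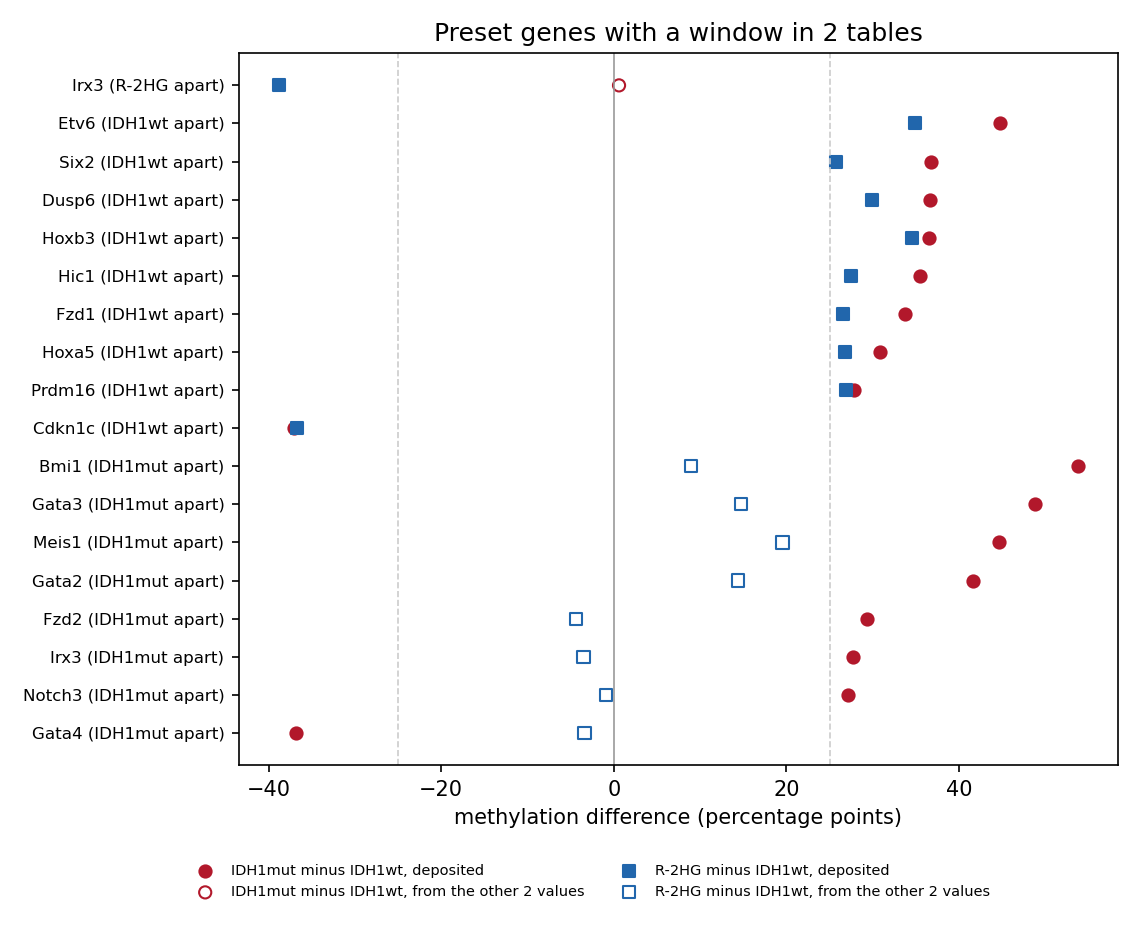
Difference against IDH1wt (x axis, percentage points) for preset genes with a window in 2 tables, IDH1mut as red circles and R-2HG as blue squares, filled where deposited and open where obtained by subtraction. At Bmi1 the circle lies at 53.7 and the square at 8.96, while at Cdkn1c they lie at -37.0 and -36.7, under the sign reading given in the methods.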

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

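The tests of explanations in this part were chosen after the results were seen. A difference between IDH1mut and R-2HG marked the following values, tested by the authors' own comparison of the 2 groups. Of the windows listed for IDH1mut against IDH1wt, 251 were also listed between IDH1mut and R-2HG. In all 251 R-2HG lay closer to IDH1wt than IDH1mut did, which subtraction fixes wherever R-2HG was not listed against IDH1wt. Of the windows listed for R-2HG against IDH1wt, 75 were also listed in that comparison. In the authors' deposited table R-2HG minus IDH1mut was -44.8 points at Bmi1, -33.8 at Fzd2, -27.2 at Gata2, -34.0 at Gata3, 33.4 at Gata4, -25.1 at Meis1 and -28.1 at Notch3. At Irx3 it was -31.2 points where IDH1mut stood apart and -39.4 where R-2HG did, in the authors' deposited table. The vector is confounded with the treatment in each of these.

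IDH1wt stood apart from the other 2 groups more often than either of them did. A lower bisulfite conversion in 1 group shifts all windows one way, and 23.5% of these clusters (95% interval 18.2 to 29.5) lay on the less frequent side, so it cannot be the whole cause. Noise of equal size in 3 unchanged groups stays open, since the 53.8% of clusters (49.0 to 58.6) all rest on the same 2 libraries per group. Fewer reads in the IDH1wt libraries stay open too: a p of 0 in both tables was found for 69.1% of windows with IDH1wt apart and 81.5% with IDH1mut apart, but p also depends on the size of the difference, and coverage is unknown. A change shared by mutant IDH1 and R-2HG, an effect of the IDH1wt transgene and 1 deviating IDH1wt library were not tested.

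Gains outnumbered losses in both comparisons against IDH1wt. Reads shared between copies at olfactory, vomeronasal, microRNA, predicted and pseudogene models are not the whole cause, since without these models gains made up 66.6% of clusters for IDH1mut and 64.0% for R-2HG. Other genes with near-identical copies, such as Ubb, were kept. Windows with little read support stay open: where p was 0 gains made up 70.9% and 73.4% of clusters, and where it was above 0 59.9% and 52.3%, but p also rises with smaller differences and gains were the larger ones. Both comparisons rest on the same 2 IDH1wt libraries, so a deviation of those libraries could give both excesses and was not tested.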

How the results depend on the processing

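No paired analysis was possible because the tables hold no value per library. For the same reason leaving out a library and a coverage minimum were not run, nor was joining the strands of a CpG, since the tables hold windows. Depth is unknown and limits every value in a way that cannot be measured here. Of 70 alternative values for 25 results, 43 stayed within the limits set for them. The shares of gains kept their direction and passed the exact test under every alternative chosen beforehand. With a difference of at least 40 points, 211, 75 and 58 windows were listed for IDH1mut against IDH1wt, R-2HG against IDH1wt and R-2HG against IDH1mut, with 5, 1 and 3 preset genes, and 39 windows were shared against IDH1wt; fewer windows enter by construction. Counted as clusters the lists held 927, 468 and 379. Within 50 kb, 10 preset genes were listed for R-2HG. By gene, not window, 255 were shared and 240 moved the same way. For IDH1mut the promoter odds ratio was 1.51 from -5000 to 1000 bp (Fisher's exact test, p = 0.0223, adjusted p = 0.0670 over the 3 comparisons) and 1.44 from -1000 to 1000 bp (p = 0.0576, adjusted p = 0.173, same exact test), so neither passed after adjustment; the cause was not tested. The following alternatives were chosen after seeing the data. The other reading of the sign turned the shares of gains to 32.9, 34.2 and 63.6%. In promoter windows 8, 4 and 4 preset genes were listed. IDH1wt, IDH1mut and R-2HG stood apart in 234, 155 and 46 clusters, and with 30 points in both tables in 175, 104 and 27 windows.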

Other observations

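The regions and families in this part were chosen after their values were seen, as was the test of the sign. Near Hoxb3 and Hoxb4, 5 of 5 listed windows were gains for IDH1mut in the authors' deposited table, and near Hoxb3 and Hoxb5 6 of 6 for R-2HG. All 10 listed windows near Hoxc5 and Hoxc6 were losses for IDH1mut, of -29.9 to -58.1 points in the authors' deposited table (chromosome 15, 102835751 to 102843000), and all 6 near Hoxc6 for R-2HG. Neighbouring windows share CpGs, so these are few independent regions, and windows past no threshold are unknown.

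Over all clusters gains made up 67.1% for IDH1mut and 65.8% for R-2HG, and the 95% interval of each family below included that share. Near microRNA genes 13 of 15 clusters were gains for IDH1mut (86.7%, 95% interval 59.5 to 98.3) and 9 of 11 for R-2HG. Mir684-1 alone had 3 of the clusters for IDH1mut, on chromosomes 16, 2 and 5. Near olfactory receptor genes 6 of 6 and 3 of 3 clusters were gains. Near zinc finger genes named Zfp 14 of 22 and 10 of 16 were gains (63.6% and 62.5%). Ubb and its pseudogene Ubb-ps, listed as Gm1821, both gained in R-2HG, by up to 61.2 and 30.9 points in the authors' deposited table, and both values are uncertain because the copies share sequence.

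The direction of the whole set may be the reverse of the reading used. Clusters within 500 bp of a start site, mostly unmethylated in normal cells, were gains in 72.7% for IDH1mut (95% interval 64.5 to 79.9), against 66.5% elsewhere (63.2 to 69.8). Both readings allow this, and they cannot be told apart because the tables hold differences without group means.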
